A study of Mus musculus with 6 samples.

How the data were processed

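The series holds 6 arrays of mouse primary hepatocytes, 3 treated with GW4064 and 3 with DMSO, and sample titles gave each array its group and replicate number. Per the labels' protocols, total RNA was labelled with biotin and measured on 1-colour Affymetrix MoGene-2_0-st arrays, and the series design text names 3 independent preparations. The deposited values are log2 intensities per probe set, normalized by the authors with RMA, and Partek is also named, both per the submitters' processing notes and without versions. The log base is not stated, and log2 was taken from the range of the values, 0.94 to 13.07, which is that of RMA output. Replicates were not pooled, and no 2 arrays were identical.

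The table holds 41345 probe sets. The platform annotation used here gives 23521 of them exactly 1 gene symbol, 1814 several symbols and 16010 none. Only probe sets with 1 symbol were named. For a gene with several of these (1082 genes) the one with the highest mean over all 6 arrays was kept, which left 22180 genes. Entrez identifiers of 21994 genes were found in the RefSeq gene table, where no symbol differed, and 186 were not. No genome build is given in the sources used here, and no coordinates are reported.

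Differences between GW4064 and DMSO were fitted on the deposited log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no block and no filter on dim genes, and p-values were adjusted by Benjamini-Hochberg over all genes. Folds are 2 to the power of the log2 change, with 95% intervals from limma's moderated standard errors. Unless stated otherwise, intervals and SE come from the fit without the block, also where a blocked p stands beside them. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so single genes were tested with limma only. The 33 gene lists were tested with limma's camera at a preset correlation of 0.01 (two-sided, adjusted over the 33 lists), with camera at an estimated correlation, and with fry (statmod 1.5.0). List members were also adjusted over the list alone. Of 628 listed symbols, 567 were matched to a tested gene and 61 were not.

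The comparison, its test, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule names 10 genes chosen for their known part in the FXR response, up to 12 genes per direction with the largest change among those past the threshold and alike in sign in all same-numbered pairs, leaving out predicted and small-RNA genes, and up to 4 members of each list with the smallest p. Where a direction held fewer than 10 such genes it was filled from the fit with the replicate block, which gave only Fezf1 for the lowered genes. Mir122 and Mir1960 fall outside the rule and are named to complete small counts. Abcc2, Abcg8, Nr2f2, Ugt2b5, Hmox1, Ppargc1a, Pnpla3, Vnn1, Ccl2, Hamp, Ier3 and Igfbp1 were named after their values were seen, to complete the calls over a list alone that change with the block.

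Same-numbered arrays were checked for pairing. The correlations of their deviations from the group means were 0.26, 0.34 and 0.45 for replicates 1, 2 and 3, every array correlated best with its own number, and the preset rule asks for more than 0.1 in every pair. The numbers come from the titles, and no label says that a number marks a preparation. The fit with the replicate block is therefore given beside a result wherever it changes the call.

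The fits were tested on simulated data with the means and replicate shifts of the 22180 genes and 200 genes changed in each of 5 simulations. With gene variances drawn from the fitted prior, the fit without the block recovered 2.99%, 83.0% and 99.4% of genes changed by 0.5, 1 and 2 on the log2 scale, with 9 false calls among 625. The blocked fit recovered 13.4%, 92.5% and 100%, with 42 false among 728. The simulation was first run with each gene's variance set to its own shrunken estimate. There the blocked fit made 104 false calls among 1071 and recovered 84.5% at 0.5, against 2 false among 664 and 5.97% without the block. The prior was chosen after that result was seen. Blocked calls carried the larger false share under both choices. That share lay close to the threshold of 0.05 with the prior and above it with the shrunken estimates. The simulated replicate shifts were the observed ones, noise included, and the fit without the block leaves them in its spread. These shares therefore do not settle how reliable the genes called only with the block are. A list of 20 genes shifted by 0.3 was found by camera in 5 of 5 simulations, and 4 of 200 unshifted lists passed an unadjusted p of 0.05 without the block and 8 with it, with variances drawn from the prior. The simulated noise was independent between genes, whereas the estimated correlation of the cholesterol synthesis and uptake list was 0.80. These counts therefore do not give camera's false rate for lists of correlated genes.

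Alternatives were quantile normalization, centring each array on its median, filters at the 25th percentile and at the median of gene level, the mean of a gene's probe sets, all probe sets, eBayes with trend or robust, array weights, other thresholds, the replicate block, and leaving out each array and each same-numbered pair. The 17824 probe sets with no symbol or several were fitted apart from the genes.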

Results

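Primary hepatocytes from adult male C57Bl/6 mice were kept in serum-free William's medium and exposed for 4 h to 2 µM GW4064, a synthetic agonist of the bile acid receptor FXR (gene symbol Nr1h4), or to the solvent DMSO. RNA from 3 preparations was measured on 6 one-colour Affymetrix arrays, 3 per group, which asks which hepatocyte genes the agonist regulates. The deposited RMA values ran from 0.94 to 13.07 on the log2 scale, and the array medians lay within 0.053 of each other. The median log2 change over all 22180 genes was -0.016. The number of arrays limits the precision of every value below.

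GW4064 raised 11 genes, led by Abcb11 (probe set 17386177), which encodes the bile salt export pump of the canalicular membrane. Its level went from 4.88 ± 0.18 to 7.97 ± 0.17 (mean log2 intensity ± SD, n = 3 arrays each), an 8.47-fold rise with a 95% interval of 6.94 to 10.4 and a limma adjusted p of 3.70e-05. Nr0b2 (probe set 17419622), the atypical nuclear receptor SHP that represses other nuclear receptors, rose 5.18-fold from 4.51 ± 0.06 to 6.89 ± 0.22 (95% interval 4.29 to 6.27, adjusted p = 1.17e-04). Mybl1, a transcription factor of the MYB family, rose 4.55-fold, and Nr1i2, the xenobiotic receptor PXR, rose 3.30-fold. Abcb4, which moves phosphatidylcholine into bile, rose 2.44-fold.

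The remaining rises lay between 1.83-fold and 2.84-fold. Wipf3, a gene of the WASP-interacting protein family, rose 2.36-fold (adjusted p = 0.0166), and the galactosyltransferase gene B4galt5 rose 2.22-fold (adjusted p = 0.0177). The scaffold gene Shank2 and the mitochondrial carrier gene Slc25a47 rose 1.99-fold and 1.95-fold. Insig2, whose product holds the sterol-regulated SREBP proteins in the endoplasmic reticulum, rose 1.83-fold from a high level of 8.86 ± 0.05 to 9.73 ± 0.04. The probe set carrying the symbol of the microRNA gene Mir122 rose 2.84-fold (adjusted p = 0.0451), and it is named because it completes the 11, after its value was seen. All 11 were higher with GW4064 in each of the 3 same-numbered pairs, and 8 of them changed at least 2-fold.

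**Figure D1:**
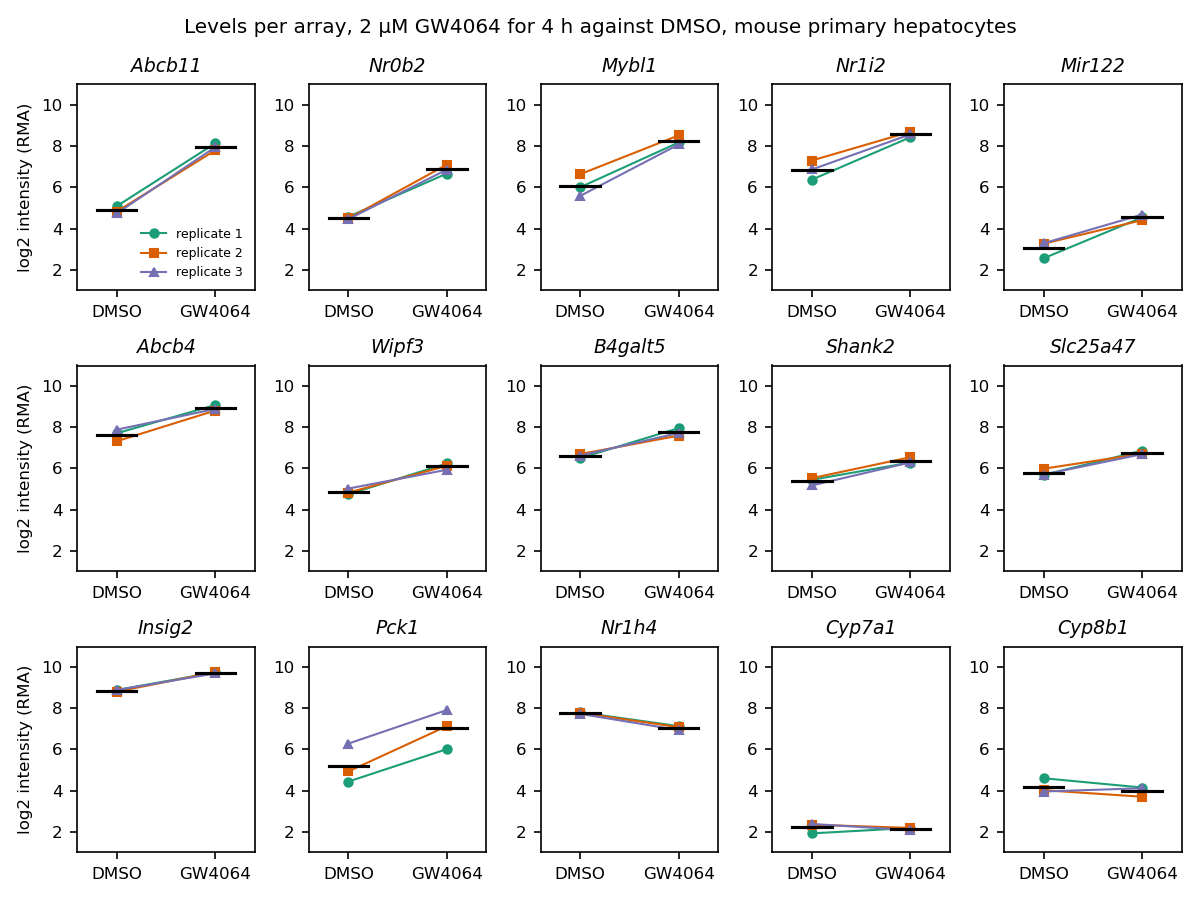
Log2 intensity (RMA, vertical axis from 1 to 11) in each of the 6 arrays for the 11 raised genes and for Pck1, Nr1h4, Cyp7a1 and Cyp8b1. Points and lines join arrays with the same replicate number, and black bars are group means of 3 arrays. Abcb11 moved from a mean of 4.88 to 7.97, Pck1 moved up in each pair from different starting levels, and Cyp7a1 lay near 2.2 in both groups.

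No gene was lowered at a limma adjusted p under 0.05, against 678 lower and 577 higher at an unadjusted p under 0.05, where 1109 in all would be expected with no change. The closest was Nr1h4 itself, the gene of the receptor that GW4064 binds, with a log2 change of -0.72 (SE 0.09, adjusted p = 0.0535) and a lower level in all 3 pairs. With the replicate number as a block, limma called 18 genes, 16 raised and 2 lowered. The lowered pair were Fezf1, a zinc-finger transcription factor gene, and the microRNA gene Mir1960. Fezf1 had a log2 change of -0.98 (blocked adjusted p = 0.0488, against 0.928 without the block). Its differences in same-numbered pairs 1, 2 and 3 were -0.784, -0.998 and -1.153. With arrays left out its change was -1.53 to -0.53, where dropping a single array also breaks a pair. Mir1960 had -1.14 (blocked 0.0374, against 0.0779). The 2 sets shared 8 genes, and B4galt5, Slc25a47 and Mir122 missed the threshold with the block (adjusted p = 0.0570, 0.0618 and 0.0570). With each array left out in turn, Abcb11 and Nr0b2 stayed past the threshold every time and each of the other 9 genes dropped out at least once, the total falling to between 2 and 5.

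**Figure D2:**
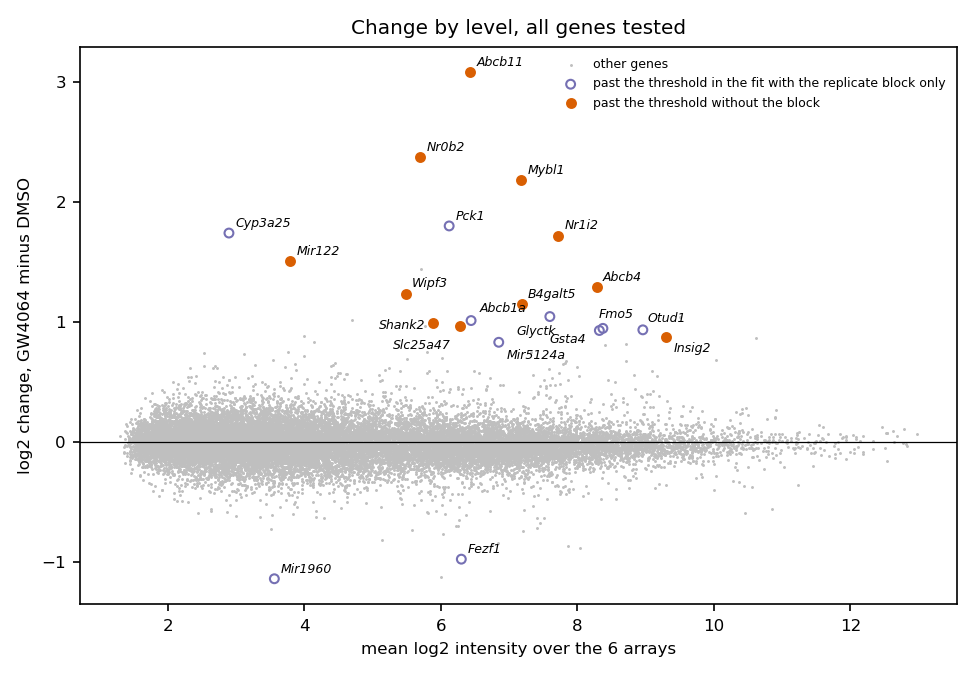
Log2 change, GW4064 minus DMSO (vertical axis), against the mean log2 intensity over the 6 arrays (horizontal axis) for the 22180 genes. Filled points mark the 11 genes past adjusted p 0.05 without the block, open circles the 10 genes past it only with the replicate block, and grey points the others. All 11 filled points lie above 0, and Fezf1 and Mir1960 are the open circles below 0.

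Known FXR target genes were higher as a group in limma's camera test at the preset correlation (adjusted p = 1.81e-08). They did not pass with an estimated correlation, which was 0.036 (camera adjusted p = 0.156, unadjusted p = 0.00744). Their median log2 change was 0.09. Of the 27 measured members, 19 were higher and 4 rose over all genes tested, namely Abcb11, Nr0b2, Abcb4 and Insig2. Adjusted over the list alone, 8 rose and 1 fell, and with the replicate block Abcc2 was a further rise (adjusted p = 0.0512 over the list alone, 0.0454 with the block). Mafg, a small MAF partner of NRF2, had a log2 change of 0.58 (SE 0.10) and Osgin1, an oxidative stress gene, 0.86 (SE 0.19), whereas Ppara, the fatty-acid-sensing nuclear receptor, had -0.48 (SE 0.12). Without Abcb11 and Nr0b2, a setting added after the data were seen, the camera adjusted p was 2.87e-04 at the preset correlation. This setting was not run with an estimated correlation.

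Bile acid and organic anion transporters, a list that shares Abcb11, Abcb4, Abcc2, Slc51a, Abcg5 and Abcg8 with the FXR targets, shifted upwards, with 13 of 19 measured members higher (camera adjusted p = 8.88e-07, adjusted p = 0.156 with an estimated correlation). Besides Abcb11 and Abcb4, 2 further members passed when adjusted over the list alone. These were Abcb1a, a drug efflux pump gene with a log2 change of 1.01 (SE 0.16, adjusted p = 0.123 over all genes, 0.0374 with the replicate block), and Abcg5, of the sterol exporter, with 0.47 (SE 0.13). Abcg8, its partner, passed over the list alone only with the block (adjusted p = 0.0508, 0.0398 with the block). Slc10a1, the sodium-dependent bile acid uptake carrier, had a log2 change of 0.03 (SE 0.21). Slc51a, one subunit of the basolateral organic solute transporter, lay at 2.73 ± 0.12 and 2.88 ± 0.07, low on the array scale, with a change of 0.14 (SE 0.10). Slc51b, the other subunit, has no probe set of its own in the annotation used here and entered no gene list.

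The bile acid synthesis genes did not shift (17 measured, camera adjusted p = 0.979), and the camera direction was up although 13 members, the median (-0.05) and the mean (-0.01) were below 0. Cyp7a1, the rate-limiting enzyme gene of the classical pathway, had a log2 change of -0.06 (SE 0.13), and its level of 2.22 ± 0.25 in DMSO lay near the low end of the arrays, where a fall would be hard to see. Cyp8b1, the sterol 12-hydroxylase gene, had -0.20 (SE 0.19). Akr1d1, a steroid reductase gene, was the 1 member that passed when adjusted over the list alone, with a log2 change of 0.47 (SE 0.11, adjusted p = 0.534 over all genes). Its levels of 3.02 ± 0.19 in DMSO and 3.49 ± 0.03 with GW4064 were low on the array scale. The signs of the Cyp7a1, Cyp8b1 and Slc10a1 changes turned when single arrays or pairs were left out.

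Among 28 nuclear receptor and hepatocyte transcription factor genes, 2 rose over all genes, Nr0b2 and Nr1i2. Adjusted over the list alone, 3 rose and 2 fell. Hnf4a, a master regulator of hepatocyte identity, joined the rises with a log2 change of 0.55 (SE 0.12, adjusted p = 0.393 over all genes), and the falls were Nr1h4 and Ppara. With the block Nr2f2 also passed over the list alone (adjusted p = 0.0972, 0.0468 with the block). The list had no common direction (camera adjusted p = 0.683, with a median of -0.05 and a mean of 0.11), while fry's test for change in either direction gave an adjusted p of 8.41e-05.

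Phase I drug metabolism genes shifted upwards in camera (24 measured, 16 higher, adjusted p = 0.00763), and the adjusted p was 0.799 with an estimated correlation. No member passed over all genes, 6 were higher at an unadjusted p under 0.05, and 2 passed when adjusted over the list alone. Those 2 were the cytochrome P450 gene Cyp3a25, from 2.02 ± 0.38 to 3.77 ± 0.48 (log2 change 1.74, SE 0.25, adjusted p = 0.0928, 0.00420 with the replicate block), and the flavin monooxygenase gene Fmo5, with 0.95 (SE 0.22, adjusted p = 0.512, 0.0488 with the block). The DMSO level of Cyp3a25 lies near the low end of the arrays, so the size of its change is uncertain. Alas1, the first enzyme of heme synthesis, had 0.44 (SE 0.13, adjusted p over the list alone 0.0596, 0.0122 with the block). Phase II genes did not pass without the block (25 measured, 14 higher, camera adjusted p = 0.0876) and did with it (adjusted p = 0.0218, and 0.533 with an estimated correlation). Gsta4, a glutathione transferase gene, was the 1 phase II member past the threshold adjusted over the list alone, at 0.93 (SE 0.22, adjusted p = 0.512, 0.0374 with the block), and with the block Gstm3, at 0.82 (SE 0.27), and Ugt2b5 passed over the list alone as well (0.00638 and 0.0208, against 0.178 and 0.311). The phase I adjusted p was 0.163 without genes under the 25th percentile of level, Cyp3a25 among them, 0.121 without those under the median, 0.302 without DMSO replicate 3 and 0.0759 without GW4064 replicate 2.

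NRF2 target genes shifted upwards (18 measured, 14 higher, camera adjusted p = 0.00855, adjusted p = 0.617 with an estimated correlation). No member passed over all genes, against 4 higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 3 rose and 1 fell. The rises were Gclm, the modifier subunit of glutamate-cysteine ligase, with a log2 change of 0.68 (SE 0.11), Mafg and Osgin1. The catalytic subunit gene Gclc moved the other way, with -0.36 (SE 0.10). With the block the heme oxygenase gene Hmox1 passed over the list alone as well (adjusted p = 0.0928, 0.00156 with the block). Mafg and Osgin1 also belong to the FXR target list. The adjusted p was 0.0727 without DMSO replicate 3 and 0.0583 without GW4064 replicate 2.

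**Figure D3:**
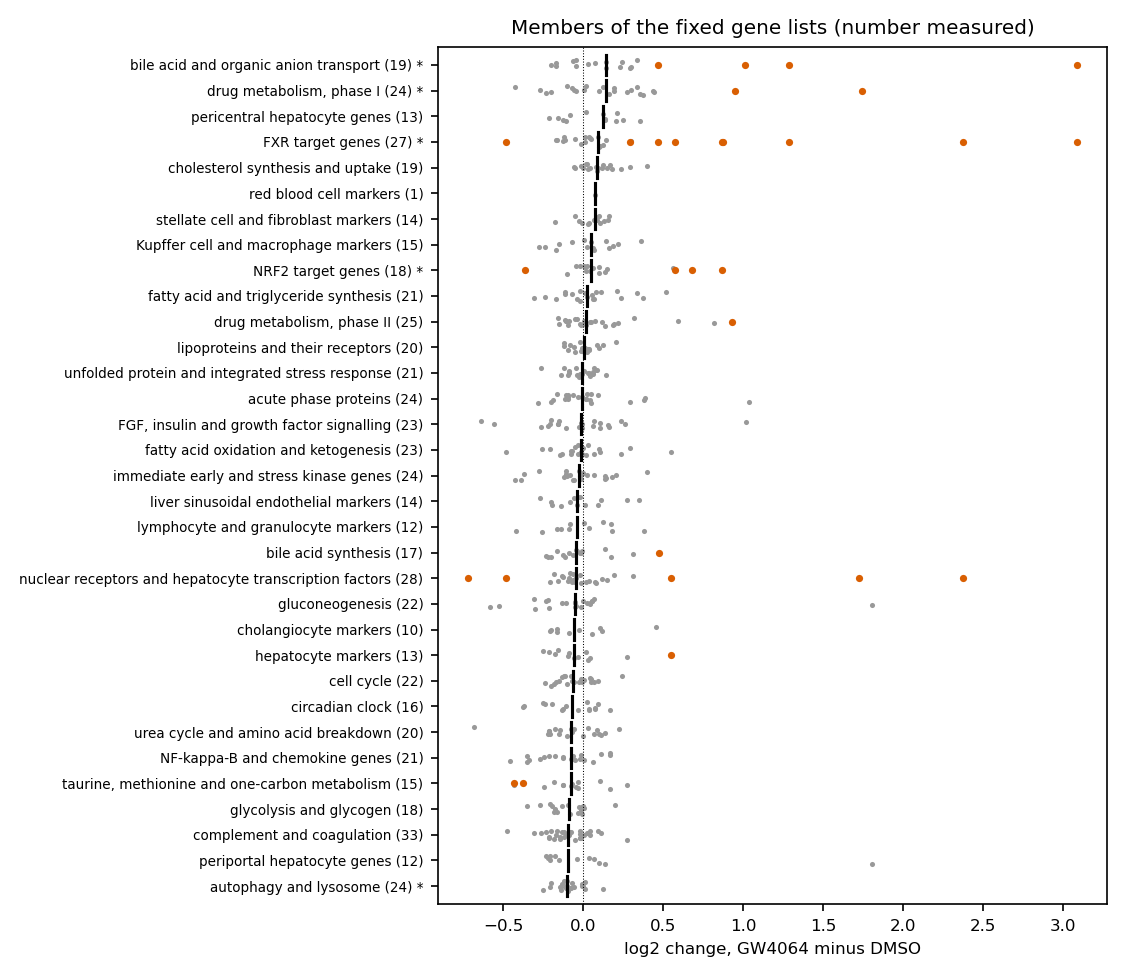
Log2 change, GW4064 minus DMSO (horizontal axis), of each measured member of the 33 gene lists, with the number measured in brackets and rows ordered by the list median (black bar). Orange points passed adjusted p 0.05 over the list alone, grey points did not, and an asterisk marks the 5 lists past camera adjusted p 0.05 at the preset correlation. The FXR target and transport lists hold the points farthest to the right, up to 3.08 for Abcb11.

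Pck1, which encodes the cytosolic enzyme that starts gluconeogenesis, was higher in all 3 pairs, from 5.22 ± 0.95 to 7.02 ± 0.95. Its fold was 3.49 with a 95% interval of 1.53 to 7.95 without the block, which takes in differences between replicate numbers. The log2 differences in pairs 1, 2 and 3 were 1.58, 2.20 and 1.63 (SE 0.14 with the block). Its starting level differed between replicate numbers, and limma gave an adjusted p of 0.689 without the block and 0.0288 with it. G6pc, the glucose-6-phosphatase gene, had a log2 change of 0.03 (SE 0.43), with a sign that turned when single arrays were left out. The other gluconeogenesis genes with small p had negative values, with Klf15 at -0.58 (SE 0.20), Foxo1 at -0.30 (SE 0.10) and Pck2 at -0.23 (SE 0.09). Over the list alone none of these passed without the block, and with it Pck1 (adjusted p = 1.55e-04), Klf15 (0.0108) and Ppargc1a (0.0113) did. The list as a whole did not pass (22 measured, 15 lower, camera adjusted p = 0.134). Glycolysis and glycogen genes (18 measured, 16 lower) had a camera adjusted p of 0.214 without the block and 0.0346 with it, the latter becoming 0.585 with an estimated correlation.

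Amino acid genes held some of the lower values. In the taurine, methionine and one-carbon list, 12 of 15 measured members were lower (camera adjusted p = 0.0876), none passed over all genes, and 2 fell when adjusted over the list alone, the second of them not with the replicate block. These were Bhmt2, a homocysteine methyltransferase gene, with a log2 change of -0.43 (SE 0.10), and Cdo1, the cysteine dioxygenase gene of taurine synthesis, with -0.38 (SE 0.10, adjusted p over the list alone 0.0387, 0.0574 with the block). Mat1a, which makes S-adenosylmethionine, had -0.43 (SE 0.17, -0.60 to -0.25 with arrays left out). Urea cycle and amino acid breakdown genes did not shift (20 measured, camera adjusted p = 0.885), with the tryptophan dioxygenase gene Tdo2 at -0.68 (SE 0.24, adjusted p = 0.797 over all genes and 0.364 over the list alone, 0.0105 with the block).

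In the lipid lists of this paragraph no member was called without the block, over all genes or over its own list. Insig2, called over all genes, is in none of them, and Ppara, of the oxidation list, passed over the FXR target list alone. Cholesterol synthesis and uptake genes were higher in 15 of 19 members, with a camera adjusted p of 0.0876, or 0.00274 with the replicate block (0.625 with an estimated correlation). Insig1 had a log2 change of 0.40 (SE 0.26, 0.22 to 0.72 with arrays left out) and the mevalonate pathway gene Mvd 0.24 (SE 0.15, 0.12 to 0.38). For fatty acid and triglyceride synthesis the camera adjusted p was 0.465, with the fatty acid synthase gene Fasn at 0.52 (SE 0.17) and Agpat2 at 0.34 (SE 0.11). With the block Fasn, Agpat2 and Pnpla3 passed over that list alone (adjusted p = 0.00842, 0.0348 and 0.0243). Fatty acid oxidation and ketogenesis and the lipoproteins and their receptors gave 0.979 and 0.952, with Vnn1 of the oxidation list past over the list alone only with the block (0.0140).

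Autophagy and lysosome genes were lower in 21 of 24 members, with a median log2 change of -0.10. The list's median level was 7.25, and all genes above the median level had a median change of -0.03. The list's camera adjusted p of 0.0491 became 0.599 with an estimated correlation. That estimate was 0.0093, below the preset 0.01, so the loss cannot be put down to a higher correlation. Before adjustment camera's p went from 0.00743 to 0.0545. In the taurine, methionine and one-carbon list it went from 0.0265 to 0.0770 at an estimate of -0.05. A larger p in this setting therefore need not reflect correlated members, in the other lists as well. None of the members passed over all genes, at an unadjusted p under 0.05 or over the list alone, and Atg5, an autophagosome gene, had the smallest p with -0.20 (SE 0.09). The autophagy call was lost in 12 of 20 alternatives. Among them were quantile normalization (camera adjusted p = 0.0852), the filter at the median of gene level (0.121), leaving out DMSO replicate 3 (0.302) and leaving out pair 2 (0.340).

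Inflammatory lists did not pass without the block. NF-kappa-B and chemokine genes were lower in 16 of 21 members (camera adjusted p = 0.0876, 0.0137 with the replicate block and 0.533 with the block and an estimated correlation), with Cxcl1 at -0.46 (SE 0.15), Cxcl10 at -0.34 (SE 0.14, -0.54 to -0.15 with arrays left out and 0.05 in pair 3), Icam1 at -0.27 (SE 0.10) and Irf1 at -0.24 (SE 0.09). With the block Cxcl1 and Ccl2 passed over the list alone (0.0334 and 0.0340, against 0.174 and 0.650). Complement and coagulation genes were lower in 26 of 33 (0.0876, 0.0109 with the block and 0.623 with an estimated correlation as well), with C6 at -0.48 (SE 0.18). Acute phase protein genes gave 0.952, with Itih3 at 0.38 (SE 0.11) and Hamp past over the list alone only with the block (0.00761, against 0.352).

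The regulatory lists without a shift in camera were the circadian clock (adjusted p = 0.465, Arntl at -0.38, SE 0.12), the immediate early and stress kinase genes (0.755, Btg2 at -0.43, Egr1 at -0.37 and Zfp36 at 0.40, each SE 0.11 to 0.12), and FGF, insulin and growth factor signalling (0.952). In the last, Fgfr2 had a log2 change of 1.02 (SE 0.26, adjusted p = 0.611) and Igfbp3 -0.64 (SE 0.25). Over the list alone none of these lists had a member past without the block. With it Arntl (0.0381), Btg2, Egr1 and Zfp36 (0.0295 each), Ier3 (0.0339), Fgfr2 (0.00183), Igfbp3 (0.00230) and Igfbp1 (0.0134) passed. The cell cycle list gave 0.641 and the unfolded protein and integrated stress response list 0.952.

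Markers of other liver cell types did not move with the treatment in camera, with adjusted p of 0.885 for cholangiocytes and for Kupffer cells and macrophages, 0.952 for sinusoidal endothelium, 0.203 for stellate cells and fibroblasts, and 0.979 for lymphocytes and granulocytes. The red blood cell list had 1 measured member and gave 0.772. Sox9, a cholangiocyte marker, had a log2 change of 0.45 (SE 0.17, adjusted p = 0.858 over all genes and 0.277 over the list alone, 0.00965 with the block). Hepatocyte markers gave 0.979, and Hnf4a was the 1 marker past the threshold adjusted over that list alone. Pericentral and periportal hepatocyte genes gave 0.395 and 0.979, and the periportal median (-0.10) and mean (0.07) differed in sign, Pck1 being a member (adjusted p over the list alone 0.0904, 8.47e-05 with the block).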

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

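The search of probe sets outside the gene comparison, with its requirement that the groups lie at least 1 log2 unit apart, was set after the first of these probe sets had been seen. Probe set 17528249, which the annotation pairs with both Slc51b and Rasl12, lay at 3.74 ± 0.68 in DMSO and 7.66 ± 0.34 with GW4064 (mean log2 intensity ± SD, n = 3 arrays each). Its log2 change of 3.93 (SE 0.35) exceeded that of Abcb11 (3.08), and the groups lay 2.92 apart. Its limma adjusted p over the 17824 such probe sets was 0.235, and 0.664 with the replicate block. The unadjusted limma p without the block was 1.32e-05, near that of Nr1i2 (1.43e-05), which was called among the genes. The 2 were fitted and adjusted apart, so their adjusted p cannot be compared. Slc51b encodes a subunit of the basolateral bile acid exporter, and the signal is assigned to neither gene here. Probe set 17208745, with no symbol, had a log2 change of 1.46 (SE 0.22, adjusted p = 0.810), from 3.66 ± 0.43 to 5.12 ± 0.12. None of the 17824 probe sets passed limma's adjusted p of 0.05 with or without the block. Without it 939 had an unadjusted p under 0.05, a share close to that threshold and so to what no change would give.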

How the results depend on the processing

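All alternatives here were planned except the lists without Abcb11 and Nr0b2 and the other splits of the arrays, which were added after the data were seen. The total of 11 changed genes became 18 with the replicate block, 18 at an adjusted p under 0.1, 2 over all probe sets and 89 at an unadjusted p under 0.05 with a 1.5-fold change. The 11 raised genes became 2 over all probe sets and 60 at the unadjusted threshold. The count of 0 lowered genes became 2 with the block, 2 at adjusted p under 0.1, 29 at the unadjusted threshold, and 1, Nr1h4, with eBayes robust, with eBayes trend and above the median level, its adjusted p ranging from 0.0282 to 0.795 over all its alternatives. The 5 moved lists became 10 with the block, 10 at adjusted p under 0.1, 3 above the median level, 2 with fry and 0 with an estimated correlation. With the block fry lost both, FXR targets going from an adjusted p of 0.0364 to 0.0663 and transport from 0.0364 to 0.141. Except where a changed threshold shows it, the cause was not tested.

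Leaving out arrays or pairs gave 2 to 5 changed and 2 to 5 raised genes, 0 to 1 lowered and 4 to 9 moved lists. The total was 3, 5 and 5 without DMSO replicates 1, 2 and 3, 2, 5 and 4 without GW4064 replicates 1, 2 and 3, and 2, 4 and 2 without pairs 1, 2 and 3. Moved lists numbered 8 without GW4064 replicate 1 and 9 without GW4064 replicate 3. Signs turned only in these settings and for 4 uncalled genes, Cyp7a1 (-0.23 to 0.054), Cyp8b1 (-0.38 to 0.00025), Slc10a1 (-0.16 to 0.23) and G6pc (-0.38 to 0.60). Dropping a single array breaks a same-numbered pair, so such ranges also take in differences between replicate numbers. Log2 changes of further uncalled genes moved more than 1.5 times, Slc51a (0.08 to 0.21), Gstm3 (0.50 to 1.00), Tdo2 (-0.89 to -0.42), C6 (-0.63 to -0.26), Igfbp3 (-0.88 to -0.39), Sox9 (0.30 to 0.60), Abcb1b (0.15 to 0.30), Cyp3a11 (0.15 to 0.88), Ugt2b5 (0.28 to 0.85), Hmox1 (0.36 to 0.75), Ppargc1a (-0.68 to -0.31), Pnpla3 (0.23 to 0.52), Vnn1 (0.36 to 0.77), Ccl2 (-0.63 to -0.09), Hamp (0.461 to 1.399), Ier3 (-0.59 to -0.21) and Igfbp1 (-0.80 to -0.24), besides those with ranges in the report. Over 84 named genes and 1502 pairs of gene and setting, 1392 kept direction and side of the threshold, 78 lost a call and 20 gained one. Beyond the calls named with the replicate block in the report and below, the block changed no other call over all genes, or of a list in camera at the preset correlation, or over a list alone, among those named here.

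Only the real grouping of the arrays gave 11 genes. The highest of the other splits gave 0, 1 of 10 splits thus reaching 11, and with the replicate block 1 of the 4 splits that part all 3 pairs reached 18, the others giving 0. These splits are too few for a share under 0.05. At an unadjusted p under 0.05, 4 of the splits that part only 1 same-numbered pair gave 1267 to 1828 genes, above the 1255 of the real grouping, so the arrays also differ by number.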

Other observations

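The genes in this paragraph were picked after their values were seen, and their adjusted p come from limma over all genes. Glyctk, a glycerate kinase gene, had a log2 change of 1.05 (SE 0.14, adjusted p = 0.0529, 0.0374 with the replicate block), and Otud1, a deubiquitinase gene, had 0.93 (SE 0.15, adjusted p = 0.122, 0.0374 with the block). Fyb2 had 1.44 (SE 0.20, adjusted p = 0.0784). The growth factor gene Hbegf and the kinase gene Sik1 had 0.75 (SE 0.12) and 0.67 (SE 0.12), with adjusted p of 0.125 and 0.176. On the lower side, the prostaglandin dehydrogenase gene Hpgd had -0.87 (SE 0.14), Acnat2, of an acyltransferase family, had -0.74 (SE 0.12), and Fam107a had -1.12 (SE 0.18), each with an adjusted p of 0.122 and lower in all 3 pairs. The Fam107a change was -0.67 with the mean of its probe sets (adjusted p = 0.176), and its adjusted p was 0.0191 without GW4064 replicate 2.

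The patterns below were all found in these data, and the tests of Abcb1a, of the second PXR list and of the number of genes over other splits were chosen after the values were seen. The second glucocorticoid list and the brightness tests were written before they were run, but with the strongest changes known. The wording of the Abcb1a explanation was narrowed, and the limit on overlap with the fixed lists was set, after the values were seen.

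Abcb1a (log2 change 1.01) lies near the strongly raised Abcb4 (1.29), with the paralog Abcb1b between them. A rise of the whole locus alike would lift the log2 value of Abcb1b as much, but Abcb1b went from 6.44 ± 0.14 to 6.67 ± 0.11 (log2 change 0.23, SE 0.11, unadjusted p = 0.0638), and the difference of the 2 changes was 0.78 (SE 0.10 over 3 pairs). The measured log2 values of the 2 genes thus did not rise alike. The test was chosen with these values known, and differences between the probe sets could add to the gap, so it gives no verdict on the locus. On unlogged intensities the mean differences were 62.8 for Abcb1a and 15.1 for Abcb1b, 47.7 apart (SE 9.15 over 3 pairs), which decides nothing on cross-hybridization from Abcb4, since the probe sets differ and their sequences were not used here. Cross-hybridization therefore stays open, and so does regulation of Abcb1a by the treatment.

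Genes known to respond to glucocorticoids were lower in 14 of 15 cases on a list put together after their values were seen, among them Tsc22d3 at -0.42 (SE 0.11), Zbtb16 at -0.39 (SE 0.10) and Fkbp5 at -0.38 (SE 0.11), with no member past an adjusted p of 0.05 over all genes. The list's camera p was 2.87e-07, or 0.0612 with an estimated correlation. A second list of 19 genes, written without looking up its members but knowing which genes were among the strongest falls, had a median of 0.01 and a camera p of 0.836, so the first result is consistent with members having been chosen for falling. Lists matched on brightness had a median of -0.02 against -0.10 for both lists together, and a share of 2e-04 of 10000 were as low, which decides nothing on genes partly picked for the fall. A hypothesis that GW4064 lowers glucocorticoid-responsive genes found no backing in the second list and stays open.

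Genes known to respond to PXR, whose gene Nr1i2 rose, were higher in 10 of 10 cases on another list put together after their values were seen, with Cyp3a25 at 1.74 (SE 0.25), Gsta4 at 0.93 (SE 0.22) and Cyp3a11 at 0.44 (SE 0.37, adjusted p = 0.994), and a camera p of 2.19e-16, or 0.0124 with an estimated correlation. A second list of 19 genes had a median of -0.05 and a camera p of 0.787. Of its members 7 were higher and 12 lower, and 0 had an unadjusted limma p under 0.05 without the block. With the block some higher and some lower members had an unadjusted limma p under 0.05, and the list's camera p was 0.699. As a list these genes did not share the rise. The second list says little on the class, since 12 of its members come from the fixed lists whose top members had gone into the first list, which tilts it against a rise. Matched on brightness, 1e-04 of 10000 random lists were as high as both lists together, the smallest share they can give, and this too rests on picked genes. Whether GW4064 raised PXR-responsive genes as a class, or single genes among them, may be asked again with a list written in advance.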
